A study of Mus musculus with 6 samples.

How the data were processed

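RNA of mouse hepatocytes was prepared as stranded, poly(A)-selected libraries (TruSeq stranded mRNA per the labels) from 6 samples in 3 groups of 2: adults on normal chow, adults on a DDC diet for 4 weeks, and embryonic day 18 livers pooled from about 8 embryos per sample. The deposited table gives TPM, transcript abundances scaled to a fixed sum, for 48432 genes and 6 samples, and each column sums to 1000000 over the genes listed. The submitters' processing notes name bcl2fastq 2.17.1.14, Trimmomatic, STAR 2.4.2a, Picard 1.119, HTSeq, DESeq2 and Cuffdiff 2.2.1 and the build GRCm38 (mm10), with no role for each. The tool behind the table, its filters and the annotation release are not given in the sources used here. The table holds no counts, so the depth of each sample and the counting error of a low value are unknown, and reads were not analysed here. Columns are numbered 0 and 1 and the sample titles 1 and 2, so columns were assigned to groups and not to single titles.

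Gene identifiers were matched to GENCODE M21 on GRCm38, which held 48053 of the 48432. Of the genes, 24885 were above 0 in some sample. Genes with at least 1 TPM in at least 2 of the 6 samples were tested, 14307 in all. Values were log2(TPM + 1). A linear model with 1 mean per group was fitted to all 6 samples with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with 3 residual degrees of freedom per gene and empirical Bayes variances that follow the mean. P-values are two-sided and were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. No counts being at hand, edgeR and DESeq2 were not used. The 3 comparisons were DDC fed against normal fed adults, E18 against normal fed adults, and DDC fed adults against E18. The first 2 share the normal fed samples, and the genes changed in both were compared with lists of the same sizes drawn independently, by Fisher's exact test, and with 100 simulated draws of unchanged groups against shared controls.

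Gene lists of pathways, functions and cell types were written from general knowledge. Of 49 lists 47 had at least 5 members tested. Each was tested with camera in limma, which compares its members with all other genes, with a preset correlation between genes of 0.01 and adjustment over the lists. The same test with the correlation estimated from the residuals, and the self-contained test fry, are given beside it. Members were also adjusted over their list alone.

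Named genes followed a rule. Part (a) is a fixed panel. Part (b) takes the 8 genes with the largest rise and the 8 with the largest fall in each comparison with normal fed adults, and 5 and 5 for DDC fed adults against E18. They had to pass the threshold with groups that did not overlap and a mean of at least 10 TPM in the higher group, with predicted genes left out. Part (c) takes up to 4 members with the smallest adjusted p of each list described, and all members where a count is 5 or fewer. As a departure, genes for which a compared group is listed at 0 were left out of part (b), since 63 genes with at least 100 TPM elsewhere are at 0 in both samples of a group. The groups, comparisons, tests, lists, the rule and most alternatives were chosen before the data were examined.

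The alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 TPM, median-ratio scaling, quantile normalization, TPM rescaled without the 50 highest genes and the erythroid genes, the replicate number as a term in the fit, only the compared groups in the fit, other variance priors, an adjusted p of 0.01, a fold change of at least 2, and each sample left out in turn. Leaving out genes listed at 0, taking protein-coding genes alone, correcting each sample for its trend with exon length, and splitting the normal fed samples between the 2 comparisons of the overlap were added after the data were seen. Where 1 sample is left in a group, it is assumed to vary like the other groups.

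The fit was tested on simulated data with 200 changed genes of 14307 at the spread of these samples. At a 2-fold change 10%, 6% and 8% of 50 genes were recovered in the 3 comparisons, at 4-fold 48%, 54% and 76%, and at 8-fold 76%, 78% and 84%, with 2, 6 and 2 unchanged genes called. With so few changed genes the adjusted threshold is stricter than in the data, where 37.3%, 75.7% and 64.7% of genes passed. These shares therefore do not measure the recovery in the data. A simulated list whose members were shifted was called in each comparison with the preset correlation, and with the estimated correlation its adjusted p was 0.0463, 0.171 and 0.0706. There were 20 simulated lists in all, and no other list was called by camera. The simulated genes vary independently, so this does not test the preset correlation.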

Results

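The samples were hepatocytes isolated from mouse liver, whose polyadenylated RNA was sequenced. They fall into 3 groups of 2 samples: adults fed normal chow, adults fed a diet with DDC for 4 weeks, and livers of embryonic day 18 (E18), where each sample was a pool of about 8 embryos. DDC is a porphyrin-inducing compound that injures the liver when fed over weeks, after which the liver regenerates. The labels do not say whether the 2 adult samples of a group came from separate animals, so the p-values given here measure only the spread between these samples. Samples are called 0 and 1 within their group, as the columns of the deposited table number them. Values are in TPM, transcript shares that sum to 1000000 in each sample, given as mean ± SD of the 2 samples of a group, and fold changes are log2 values ± SE. The depth of the samples is unknown, because the table holds no read counts.

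The normal fed samples had 10792 and 10401 genes at 1 TPM or more, the DDC fed samples 12204 and 12322, and the E18 samples 13983 and 13748. Over the 14307 genes tested, the Pearson correlation of log2 values between the samples of a group was 0.975 for normal fed, 0.991 for DDC fed and 0.986 for E18. These are correlations across genes, which are not independent replicates. The median absolute log2 difference between the 2 samples of a group was 0.37 for normal fed, 0.125 for DDC fed and 0.17 for E18. In the fit all groups share 1 variance per gene. Leaving out a normal fed sample takes the larger spread of that group out of the variance, so a gene can then pass at a smaller fold change. The difference between the normal fed samples followed the total exon length of the gene (Spearman rho = -0.404 across 10048 genes). Sample 1 minus sample 0 had a median of -0.63 in the 20% of genes with the longest total exon length and 0.03 in the 20% with the shortest. In 63 genes with at least 100 TPM in some sample, both samples of a group were listed at 0. Ahsg, a plasma protein, was listed at 10349 and 6763 TPM in the normal fed samples and at 0 in the DDC fed and E18 samples. Apoa1 was listed at 0 in all adult samples and at 10209 and 6372 TPM at E18, and albumin (Alb) was listed at 0 in all 6 samples. Ahsg, Apoa1 and Alb were picked as examples after their values were seen, and no fold change is given against a group listed at 0.

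DDC fed against normal fed adults asks which genes differ in the samples of adult hepatocytes after 4 weeks of DDC feeding. Krt8 and Krt18, the keratins that form the intermediate filaments of hepatocytes, rose from 96.4 ± 47.2 and 159.6 ± 5.91 TPM to 1988 ± 125 and 1803 ± 24.2 TPM (4.44 ± 0.42 and 3.49 ± 0.33, adjusted p = 0.00045 and 0.00044). Lcn2, a secreted siderophore-binding protein of the acute phase, rose from 6.85 ± 2.30 to 3757 ± 588 TPM (8.93 ± 0.29, adjusted p = 8.9e-06). Sox9, a transcription factor of bile ducts, rose from 1.64 ± 0.14 to 16.2 ± 5.07 TPM (2.68 ± 0.27, adjusted p = 0.00055), and the ductular marker Spp1 rose from 1.91 ± 0.14 to 62.1 ± 7.83 TPM (4.43 ± 0.23, adjusted p = 5.1e-05). Among the falls were Mup21, a major urinary protein, from 4723 ± 88.4 to 34.5 ± 1.64 TPM (-7.06 ± 0.18, adjusted p = 3.9e-06), and Cyp2e1, a cytochrome P450 of pericentral hepatocytes, from 6291 ± 2690 to 815 ± 124 TPM (-2.89 ± 0.42, adjusted p = 0.0023).

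By the ranking, the other largest rises were of Ly6d (8.79 ± 0.30), Cyp2a4 (8.65 ± 0.35), the protease inhibitor Slpi (8.44 ± 0.21), Ubd (7.86 ± 0.23), Sprr1a (7.85 ± 0.24), the calcium-binding protein S100a11 (7.67 ± 0.20) and Ifi27l2b (7.34 ± 0.40). The other largest falls were of Hsd3b5 (-7.46 ± 0.23), Sult2a8 (-7.39 ± 0.30), Elovl3 (-6.66 ± 0.24), Ces3b (-4.79 ± 0.33), Sult5a1 (-4.69 ± 0.45), Cyp8b1 (-4.57 ± 0.23) and Ugt2b38 (-4.55 ± 0.19). The rule that picked these genes required both samples of a group to lie above both of the other. On GRCm38, Krt8 (ENSMUSG00000049382.9) lies on chromosome 15 from 101996698 to 102004482, Lcn2 (ENSMUSG00000026822.14) on chromosome 2 from 32384633 to 32388252, and Mup21 (ENSMUSG00000066153.2) on chromosome 4 from 62147932 to 62150863, all as protein-coding genes. Reads of closely related genes, such as those of the Mup, Cyp2a, Cyp2c, Gsta and Gstm families, are hard to assign to 1 member.

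**Figure D1:**
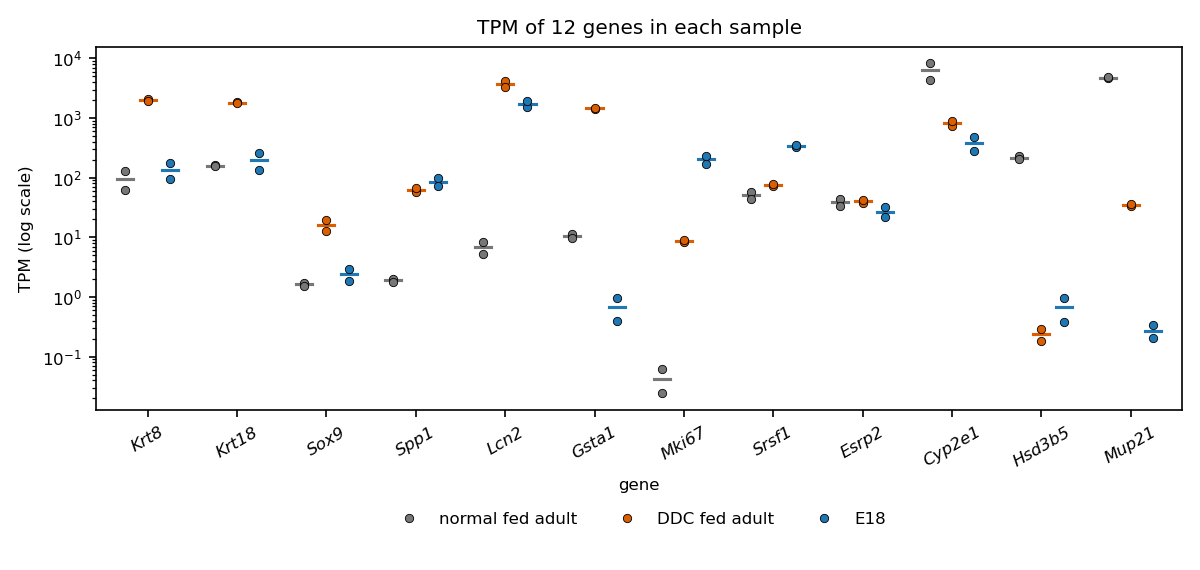
TPM (log scale) of 12 genes in each of the 6 samples; points are samples and bars are group means. Krt8, Krt18, Sox9 and Lcn2 lie highest in the DDC fed samples, Mki67 and Srsf1 at E18, and Cyp2e1, Hsd3b5 and Mup21 in the normal fed samples, while Esrp2 spans 21.6 to 44.5 TPM over all 6 samples.

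Genes of cell division rose together with DDC. Whether they rose in hepatocytes or in other liver cells, whose markers also rose, was not tested. Of 44 members of the G2/M and mitosis list, 43 rose and 1 did not pass (42 rose with median-ratio scaling), among them Cdk1 from 1.91 ± 0.49 to 65.6 ± 2.88 TPM (4.53 ± 0.21, adjusted p = 3.7e-05) and Top2a from 0.118 ± 0.04 to 22.7 ± 0.31 TPM (4.41 ± 0.22, adjusted p = 4.1e-05). Of 40 members of the G1/S and DNA replication list, 33 rose, 1 fell and 6 did not pass (26 rose and 1 fell with median-ratio scaling). Gins2 of the replicative helicase rose (3.43 ± 0.20), as did Mcm6 (4.48 ± 0.32), whereas Mcm10 fell from 216 ± 59.0 to 12.2 ± 2.82 TPM (-4.03 ± 0.29, adjusted p = 0.00017). Relative to other genes both lists were higher (camera adjusted p = 2.5e-16 for G2/M and 3.8e-06 for G1/S). With an estimated correlation the adjusted p was 0.844 for each. Adjusted over the list alone, 43 and 35 members rose. Ccnd1, the cyclin of the G1 phase, rose from 25.6 ± 11.9 to 106 ± 1.85 TPM (2.09 ± 0.33, adjusted p = 0.0032), and Mki67 rose from 0.0428 ± 0.026 to 8.68 ± 0.49 TPM (3.21 ± 0.22, adjusted p = 0.00015).

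Few splicing and translation genes passed the test with DDC, and the counts changed when 1 normal fed or DDC fed sample was left out. Of 21 SR and SR-like splicing factors 3 rose: Srpk2 (1.48 ± 0.24), Tra2a (0.82 ± 0.20) and Srsf5 (0.69 ± 0.21). With median-ratio scaling Srpk2 alone of these passed. Of 29 hnRNP proteins 2 rose, Hnrnpa3 (0.97 ± 0.30) and Hnrnpl (0.64 ± 0.20), and with median-ratio scaling none rose and 2 fell, and the fold change of Hnrnpl was -0.04. Of 55 spliceosome core genes 4 rose, Lsm8 (1.81 ± 0.23), Prpf19, Eftud2 and Lsm2, and Lsm6 fell (-0.95 ± 0.19). With median-ratio scaling 2 rose and 6 fell. The tissue-regulated splicing factors had 6 of 23 higher, led by Srrm4 (1.97 ± 0.32), Rbpms (1.91 ± 0.27) and Rbms1 (1.72 ± 0.31), against 3 higher and 1 lower with median-ratio scaling. Camera adjusted p for the 4 lists was 0.869, 0.815, 0.271 and 0.815, and with an estimated correlation it was 0.967, 0.967, 0.864 and 0.967. Adjusted over the list alone, 1 SR, 0 hnRNP, 3 spliceosome and 4 tissue-regulated genes rose. At an unadjusted p under 0.05, 8 hnRNP genes were higher in limma, and fry gave the hnRNP list an adjusted p of 0.187. Of these genes Tra2a, Srsf5, Hnrnpa3, Hnrnpl, Prpf19, Eftud2, Lsm2 and Lsm6 did not pass without DDC fed sample 0 (adjusted p from 0.0759 to 0.275) or sample 1 (0.0553 to 0.272). Srsf5, Hnrnpa3 and Hnrnpl did not pass without either E18 sample (0.069 to 0.0888), nor Hnrnpa3 without normal fed sample 1 (0.0531).

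Esrp2, an epithelial splicing regulator of adult hepatocytes, was at 39.3 ± 7.35 TPM in normal fed and 40.5 ± 3.27 TPM in DDC fed samples (0.05 ± 0.26, adjusted p = 0.907). Srsf1 was at 50.7 ± 9.16 and 75.1 ± 4.22 TPM (0.57 ± 0.21, adjusted p = 0.0746), Nf2 had a fold change of -0.10 ± 0.23 (adjusted p = 0.784) and Csnk1d of 0.90 ± 0.29 (adjusted p = 0.0512). Of 75 cytosolic ribosomal proteins none rose or fell (limma; 1 lower at an unadjusted p under 0.05), nor did any of 48 ribosome biogenesis genes (7 higher at an unadjusted p under 0.05). With median-ratio scaling 1 and 19 of them were lower. Relative to other genes both lists were lower (camera adjusted p = 2.9e-10 and 0.0028), with an adjusted p of 0.844 each with an estimated correlation. Fry, which does not compare with other genes, gave 0.820 and 0.594. The median fold change of ribosome biogenesis, 0.15, has the opposite sign to its camera test. Of 44 translation factors Eif6 alone rose (1.61 ± 0.20; camera adjusted p = 0.0897, and 0.844 with an estimated correlation), and 5 fell with median-ratio scaling. Without normal fed sample 0 the fold change of Srsf1 was 0.75 and that of Csnk1d 1.32. Without normal fed sample 1 the fold change of Csnk1d was 0.47. Leaving out normal fed sample 0 gave 13 SR, 25 hnRNP and 25 spliceosome genes higher, with 7 spliceosome genes and 38 ribosomal protein genes lower; 18 tissue-regulated factors, 21 ribosome biogenesis genes and 21 translation factors were higher then. Leaving out normal fed sample 1 instead gave 4, 2 and 9 higher, and 3 and 0 lower. Leaving out DDC fed sample 0 or sample 1 gave 1, 0 and 1 higher. By camera, the hnRNP list was higher without normal fed sample 0 (adjusted p = 0.0198) and ribosome biogenesis did not pass (0.194), and without normal fed sample 1 the ribosomal proteins did not pass (0.543). With median-ratio scaling the SR, spliceosome and translation factor lists were lower than other genes (camera adjusted p = 0.0493, 0.0071 and 0.00077). The translation factor list was also lower with rescaling without the highest genes and erythroid list (0.0263), with the exon-length correction (0.0296) and by camera on ranks (0.0104).

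YAP/TEAD targets and cytoskeletal genes were higher with DDC. Here too, whether the rises lie in hepatocytes or in other liver cells was not tested. Of 22 YAP/TEAD targets 15 rose and 7 did not pass (15 rose and 1 fell with median-ratio scaling), including Ccn2 from 0.988 ± 0.36 to 17.1 ± 3.76 TPM (3.18 ± 0.24, adjusted p = 0.0002), Nt5e (3.45 ± 0.22) and Tgfb2 (2.12 ± 0.14). The camera test gave an adjusted p of 0.0027, and 0.844 with an estimated correlation. Yap1 itself was at 29.5 ± 9.39 and 37.6 ± 0.24 TPM (0.37 ± 0.29, adjusted p = 0.345), and passed without normal fed sample 0 (0.69, adjusted p = 0.049). Of 37 genes of intermediate filaments, junctions and cytoskeleton all 37 rose (31 with median-ratio scaling), with Cd63 (7.34 ± 0.19), the galectin Lgals1 (6.08 ± 0.19) and Tmsb10 (5.35 ± 0.20) near the top. By camera the adjusted p was 4.6e-13, and 0.756 with an estimated correlation. Of 27 fetal liver genes 14 rose (14 rose and 1 fell with median-ratio scaling), such as H19 from 0.0795 ± 0.05 to 47.2 ± 8.71 TPM (5.47 ± 0.18) and Spink1 (6.59 ± 0.26). Afp reached 3.22 ± 0.06 TPM (1.85 ± 0.10). Camera adjusted p was 0.0049, and 0.844 with an estimated correlation. Without DDC fed sample 0 or sample 1, 9 fetal genes rose. The camera test gave an adjusted p of 0.293 for the fetal list without normal fed sample 0 and 0.0506 for YAP/TEAD targets without normal fed sample 1.

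Detoxification genes split. Of 33 NRF2 targets, the genes of the antioxidant response, 27 rose, 1 was lower and 5 did not pass (22 higher and 1 lower with median-ratio scaling). Gsta1, a glutathione transferase, rose from 10.4 ± 1.13 to 1445 ± 46.3 TPM (6.99 ± 0.23, adjusted p = 8.9e-06), Nqo1 from 3.32 ± 0.09 to 65.5 ± 1.31 TPM (3.94 ± 0.19, adjusted p = 3.6e-05), and Cbr3 (5.14 ± 0.19) and Srxn1 (4.42 ± 0.23) rose too. The member that was lower, Gstm1, is listed at 0 in the DDC fed samples. By camera the adjusted p was 5.2e-06, and 0.844 with an estimated correlation. Of 32 cytochrome P450 genes 5 rose and 5 fell (4 and 9 with median-ratio scaling): Cyp2b10, a target of the xenobiotic receptor CAR, rose from 24.7 ± 12.6 to 482 ± 60.0 TPM (4.32 ± 0.34, adjusted p = 0.00024), and Cyp2c54 fell (-1.68 ± 0.25). Cyp3a11, among those that fell, was at 3695 and 4181 TPM in the normal fed samples and is listed at 0 in the DDC fed samples. Camera adjusted p for lower was 0.00036, and 0.844 with an estimated correlation; with the exon-length correction the list did not pass (0.0913). Of 16 genes of bile acid synthesis Cyp8b1 and Cyp7b1 (-3.77 ± 0.32) fell and Cyp39a1 rose (1.11 ± 0.34; 0.50 and not past the test with median-ratio scaling), and 7 fell under that scaling. Camera adjusted p for lower was 3.2e-05, and 0.844 with an estimated correlation. Cyp7a1, the rate-limiting enzyme, did not pass (-0.53 ± 0.55, adjusted p = 0.483). Among 19 hepatobiliary transporters 7 were higher and 3 lower (6 and 5 with median-ratio scaling). The efflux pump Abcc4 (4.49 ± 0.23) and the transporter subunit Slc51b (4.11 ± 0.27) rose, and the uptake carriers Slco1a1 (-3.83 ± 0.31) and Slc10a1 (-1.47 ± 0.35) fell. Camera adjusted p for the transporter list was 0.334, and 0.864 with an estimated correlation. With normal fed sample 0 left out, 10 cytochrome P450 genes, 4 bile acid genes and 12 transporters were higher. Cyp39a1 did not pass without normal fed sample 1, DDC fed sample 0 or DDC fed sample 1 (adjusted p = 0.111, 0.164 and 0.151), nor Slc10a1 without DDC fed sample 0 or sample 1 (0.0881 and 0.1005).

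Male-biased liver genes were lower with DDC, and few genes of oxidative phosphorylation passed. Of 22 male-biased liver genes 15 fell, 2 were higher and 5 did not pass (16 fell and 2 were higher with median-ratio scaling), led by Mup21, Hsd3b5, Elovl3 and Ugt2b38. The 2 that were higher, Mup3 and Mup7, are listed at 0 in the normal fed samples. Camera adjusted p was 5.2e-19, and 0.756 with an estimated correlation. Of 24 female-biased genes 13 rose (9 with median-ratio scaling; 4 without DDC fed sample 0 or sample 1), at a camera adjusted p of 0.119, and 0.864 with an estimated correlation. That list passed with median-ratio scaling (0.0126), with the exon-length correction (0.0446) and without E18 sample 0 or sample 1 (0.0055 and 0.0059). Of 56 nuclear genes of oxidative phosphorylation 4 fell, Ndufb3 (-0.97 ± 0.24), Ndufb10 (-0.92 ± 0.24), Ndufa5 and Ndufb9, against 20 with median-ratio scaling. Adjusted over the list alone none passed (7 at an unadjusted p under 0.05). The camera test gave an adjusted p of 4.3e-17, and 0.756 with an estimated correlation. Without normal fed sample 0, 32 of these genes were lower and 4 higher, without either E18 sample 2 were lower, and without DDC fed sample 0 or sample 1 none passed. Of 37 genes of the urea cycle and amino acid catabolism 6 fell (18 with median-ratio scaling), among them Haao (-1.10 ± 0.24) and Tdo2 (-0.97 ± 0.21). By camera the adjusted p was 7.8e-09, and 0.844 with an estimated correlation. With normal fed sample 0 left out, 7 members of that list rose and 6 fell, without normal fed sample 1, 12 fell, and without DDC fed sample 0 or sample 1 none passed.

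Markers of other liver cells rose in the DDC fed samples beside these changes. All 25 macrophage markers rose (24 with median-ratio scaling), for example Cd14 from 0.982 ± 0.16 to 90.0 ± 3.59 TPM (5.52 ± 0.18, adjusted p = 9.6e-06). Of 26 stellate cell and fibroblast markers 23 rose (22 with median-ratio scaling), for example the collagen gene Col3a1 from 0.372 ± 0.16 to 37.8 ± 3.69 TPM (4.82 ± 0.20, adjusted p = 2.1e-05). Of 24 endothelial markers 23 rose (16 with median-ratio scaling), for example Plvap (3.22 ± 0.30). Of 22 cholangiocyte and ductular markers 16 rose (14 with median-ratio scaling), yet Krt19, a keratin of bile duct cells, was at 0.0241 ± 0.034 and 0.159 ± 0.097 TPM (adjusted p = 0.628). Camera adjusted p was 1.2e-10, 3.4e-09, 0.0004 and 0.00036 for the 4 lists, each 0.844 with an estimated correlation. Of 25 immediate early genes, which cell isolation can induce, 17 rose (13 rose and 1 fell with median-ratio scaling), such as Klf6 from 1.25 ± 0.68 to 98.8 ± 32.1 TPM (5.47 ± 0.31). The camera test gave an adjusted p of 0.0049, and 0.844 with an estimated correlation. Without DDC fed sample 1, 12 endothelial, 10 cholangiocyte and 10 immediate early genes rose, and without DDC fed sample 0, 13, 12 and 16.

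In all, 4896 genes were higher and 439 lower with DDC of 14307 tested (limma, adjusted p of 0.05). The median fold change over all genes was 0.45, and median-ratio scaling, which lowered fold changes by a median of 0.60, gave 2907 higher and 1700 lower, with 2906 of the 4896 and all 439 among them. By camera 12 lists were higher and 15 lower of 47; with an estimated correlation none passed (1 at an unadjusted p under 0.05), and fry called 13. Leaving out 1 sample moved the counts by over 1.5 times without normal fed sample 0, to 7985 higher and 917 lower, and without DDC fed sample 0 or sample 1, to 2442 and 2375 higher and 220 and 248 lower. The difference followed total exon length across 10048 genes (Spearman rho = 0.168). Its median was 0.23 in the 20% of genes with the shortest total exon length and 0.61 in the 20% with the longest. Against normal fed sample 0 alone rho was -0.0069, and against sample 1 alone 0.254. Alas1, the first enzyme of heme synthesis, was at 1829 and 493 TPM in the normal fed samples and 959 and 946 TPM in the DDC fed samples (adjusted p = 1). Myc at 22.9 and 2.44 TPM against 32.7 and 54.7 TPM (adjusted p = 0.0685) and Cps1 at 1681 and 495 TPM against 1391 and 1232 TPM (adjusted p = 0.51) did not pass either. Without normal fed sample 0 the fold change with DDC was 0.95 for Alas1, 3.66 for Myc and 1.40 for Cps1, and without normal fed sample 1 it was -0.94 for Alas1. Fits without a normal fed sample lack the spread between the 2 normal fed samples. Their counts therefore do not show by themselves that a result depends on which sample is used. With only the groups compared in the fit, 3792 genes were higher and 329 lower.

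**Figure D2:**
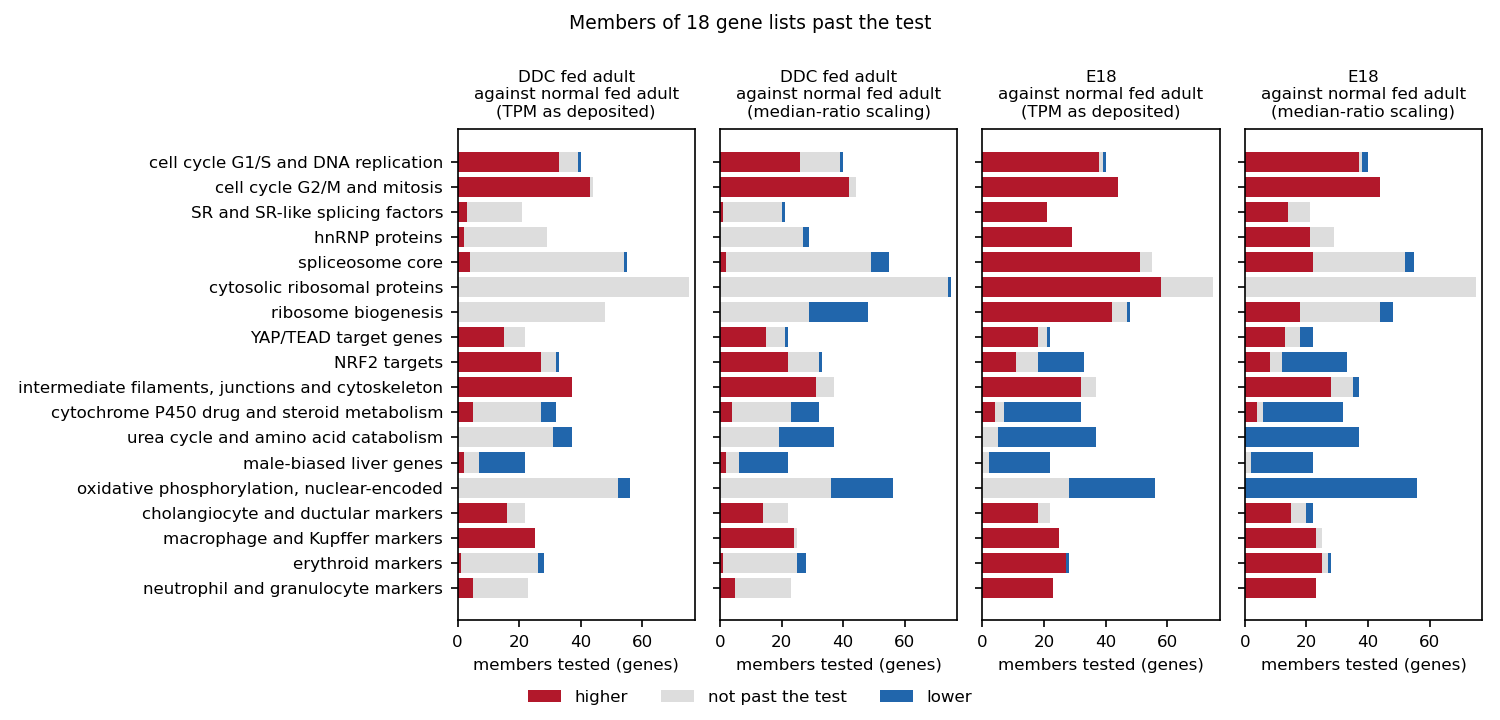
Members of 18 gene lists that were higher, lower or not past the test against normal fed adults, by TPM as deposited and by median-ratio scaling; bars count genes. G2/M genes are higher in all 4 panels (43, 42, 44 and 44 of 44), ribosomal proteins at E18 pass only without that scaling (58 against 0 of 75), and oxidative phosphorylation genes are lower in all 4 (4, 20, 28 and 56 of 56).

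E18 against normal fed adults asks which genes differ between fetal and adult hepatocytes. Igf2, the fetal insulin-like growth factor, rose from 0.0231 ± 0.02 TPM in normal fed adults to 1895 ± 558 TPM at E18 (10.82 ± 0.25, adjusted p = 9.0e-07), and the oncofetal proteoglycan Gpc3 rose to 467 ± 143 TPM (8.82 ± 0.25). Transcripts of blood cells were among the most abundant at E18: S100a8 of neutrophils was at 18173 ± 2502 TPM (13.97 ± 0.22, adjusted p = 3.5e-07) and the adult globin gene Hbb-bs at 9657 ± 3971 TPM (12.65 ± 0.33). Enzymes of the adult liver fell: Cyp2c29 from 1673 ± 624 to 0.0769 ± 0.003 TPM (-10.55 ± 0.29, adjusted p = 1.4e-06) and Tdo2, the first enzyme of tryptophan breakdown, from 1333 ± 229 to 1.48 ± 0.06 TPM (-9.06 ± 0.21, adjusted p = 9.0e-07). Srsf1, an SR splicing factor, rose from 50.7 ± 9.16 to 339 ± 20.5 TPM (2.73 ± 0.21, adjusted p = 3.1e-05).

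By the ranking, the other largest rises were of Hba-a1 (12.04 ± 0.40), Elane (9.94 ± 0.22), Cd24a (9.79 ± 0.25), Prtn3 (9.63 ± 0.23) and A2m (9.49 ± 0.26). The other largest falls were of Mup21 (-11.86 ± 0.18), Mup20 (-10.56 ± 0.25), Inmt (-9.48 ± 0.21), Ces3b (-9.34 ± 0.33), Mug1 (-9.29 ± 0.37) and Cyp1a2 (-9.13 ± 0.33). Again the rule required both samples of a group to lie above both of the other. On GRCm38, Igf2 (ENSMUSG00000048583.16) lies on chromosome 7 from 142650766 to 142666816, S100a8 (ENSMUSG00000056054.9) on chromosome 3 from 90668978 to 90670035, and Tdo2 (ENSMUSG00000028011.16) on chromosome 3 from 81957090 to 81976202, all protein-coding. Of 27 fetal liver genes 24 rose (23 rose and 1 fell with median-ratio scaling), at a camera adjusted p of 0.00025, and 0.4998 with an estimated correlation. With 1 E18 sample left out, members at 1 TPM or more only at E18 no longer met the filter and could not be tested. Afp and H19, fetal liver transcripts, are listed at 0 in both E18 samples.

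SR, hnRNP and spliceosome genes were higher at E18, and the tissue-regulated splicing factors did not pass as a list. Genes of blood-cell lists held 7.81% and 10.2% of TPM in the E18 samples. Whether the rises lie in hepatocytes or in blood cells was not tested. All 21 SR and SR-like factors rose (14 with median-ratio scaling), among them Tra2a (2.45 ± 0.20), Srsf10 (2.29 ± 0.20) and Srsf3 (2.64 ± 0.23). All 29 hnRNP proteins rose (21 with median-ratio scaling), among them Hnrnpa1 from 35.0 ± 13.5 to 580.1 ± 45.9 TPM (4.06 ± 0.28, adjusted p = 1.9e-05) and Hnrnph1 (2.47 ± 0.20). Of 55 spliceosome core genes 51 rose and 4 did not pass (22 rose and 3 fell with median-ratio scaling), among them Lsm8 (3.46 ± 0.23) and Snrnp40 (2.74 ± 0.20). By camera the adjusted p was 0.0057, 0.0041 and 0.0075, and 0.538, 0.660 and 0.545 with an estimated correlation; with median-ratio scaling the spliceosome list did not pass (0.0807). Of 23 tissue-regulated splicing factors 15 rose (10 rose and 6 fell with median-ratio scaling), with Rbm38 (5.04 ± 0.33), Celf2 (3.81 ± 0.30) and Mbnl3 (3.62 ± 0.13) in front (camera adjusted p = 0.644, and 0.892 with an estimated correlation). Esrp2 was at 26.8 ± 7.36 TPM at E18 (-0.55 ± 0.26, adjusted p = 0.0876), and was lower without normal fed sample 1 (-0.74, adjusted p = 0.0332). Nf2, a regulator of the Hippo pathway, rose from 13.1 ± 3.73 to 29.7 ± 0.19 TPM (adjusted p = 0.0037) and Csnk1d rose (1.26 ± 0.29, adjusted p = 0.0066); with a correction for exon length the fold change of Nf2 was -0.16.

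Genes of cell division were higher at E18, and the lists of translation depend on the scaling. Here too, whether the rises lie in hepatocytes or in blood cells was not tested. All 44 G2/M genes rose (44 with median-ratio scaling), for example Top2a (7.84 ± 0.22), and so did 38 of 40 G1/S genes, while Mcm10 fell (-2.73 ± 0.29; 37 rose and 2 fell with median-ratio scaling). Camera adjusted p was 1.5e-10 and 7.6e-06, each 0.538 with an estimated correlation. Mki67 reached 202 ± 43.8 TPM (7.59 ± 0.22) and Myc rose from 12.6 ± 14.4 to 98.7 ± 6.93 TPM (3.46 ± 0.81, adjusted p = 0.0069), but Ccnd1 did not pass (-0.54 ± 0.33, adjusted p = 0.173) unless normal fed sample 1 was left out (-1.01, adjusted p = 0.0029). Of 75 ribosomal proteins 58 rose as deposited and none with median-ratio scaling, where the list's median fold change was 0.11 against 1.30 (camera adjusted p = 0.196, and 0.891 with an estimated correlation). Of 48 ribosome biogenesis genes 42 rose and Nop16 fell (18 rose and 4 fell with median-ratio scaling), among them Dkc1 (2.78 ± 0.23) and Npm1 (2.49 ± 0.24; camera adjusted p = 0.0496, and 0.731 with an estimated correlation). Of 44 translation factors 34 rose, against 1 that rose and 9 that fell with median-ratio scaling (camera adjusted p = 0.324, and 0.796 with an estimated correlation). Without E18 sample 1, 33 ribosomal proteins and 22 translation factors rose, and without E18 sample 0, 42 and 21. By camera, ribosomal proteins passed without normal fed sample 1 (adjusted p = 0.00013) or E18 sample 0 (0.0209) and with the exon-length correction (0.0058). Ribosome biogenesis did not pass with median-ratio scaling (0.429), the exon-length correction (0.0786), rescaling without the highest genes (0.0557), the replicate block (0.0617) or camera on ranks (0.298), or without DDC fed sample 0 or sample 1 (0.0973 and 0.0997). Nop16 did not pass without any 1 of the DDC fed or E18 samples (adjusted p from 0.0686 to 0.128).

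Genes of adult hepatocyte function were lower at E18. Of 37 urea cycle and amino acid catabolism genes 32 fell (37 with median-ratio scaling), among them Tat (-6.99 ± 0.27). Of 32 cytochrome P450 genes 25 fell and 4 rose (26 and 4 with median-ratio scaling), the 4 being Cyp2c69 (7.75 ± 0.26), Cyp2c40, Cyp4a14 and Cyp4a10. Of 37 complement and coagulation genes 22 fell (33 with median-ratio scaling; 18 adjusted over the list alone), and of 33 hepatocyte transcription factors 15 fell and 2 rose (28 and 1 with median-ratio scaling), with Hnf4a going from 282 ± 126 to 82.5 ± 33.4 TPM (-1.75 ± 0.39, adjusted p = 0.0058). Of 56 oxidative phosphorylation genes 28 fell (56 with median-ratio scaling; 11 adjusted over the list alone). Of 22 male-biased genes 20 fell under either scaling. For that list sex differs along with age, as Xist, a transcript of female cells, was at 60.7 and 173 TPM in the E18 pools. In the adult samples Xist was at 0.0706 TPM or less. The Y-linked gene Eif2s3y was at 59.9 and 25.6 TPM in the pools and 60.2 and 66.8 TPM in the normal fed samples. Both pools thus held male cells beside female ones. How much of the fall goes with sex and how much with age was not tested. The camera test gave an adjusted p of 9.7e-24, 1.5e-17, 2.4e-14, 5.0e-11, 2.9e-17 and 1.4e-20 for these 6 lists, each 0.4998 with an estimated correlation. NRF2 targets went both ways, with 11 higher and 15 lower of 33 (8 and 21 with median-ratio scaling; camera adjusted p = 7.6e-06, and 0.4998 with an estimated correlation). Without E18 sample 1, 10 complement genes fell, and without either E18 sample 9 or 10 oxidative phosphorylation genes fell. That list had 13 lower without either DDC fed sample and 45 without normal fed sample 0, and 24 hepatocyte transcription factors fell without normal fed sample 1.

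Markers of blood cells, of other liver cells and of cell isolation also rose at E18. Of 28 erythroid markers 27 rose and Tfr2 fell (25 rose and 1 fell with median-ratio scaling), and all 23 neutrophil markers rose under either scaling, 17 of which are listed at 0 in both samples of a group. All 19 megakaryocyte, 22 hematopoietic progenitor, 24 endothelial and 25 macrophage markers rose (19, 22, 23 and 23 with median-ratio scaling), for example Pf4 of platelets from 0.546 ± 0.052 to 1038 ± 133 TPM (9.39 ± 0.19). By camera the adjusted p was 6.9e-06 for erythroid and 1.1e-08 for neutrophil markers, and 0.538 and 0.4998 with an estimated correlation. For the other 4 lists it was 1.2e-06, 2.3e-06, 0.0015 and 5.0e-05, and 0.4998, 0.4998, 0.660 and 0.538 with an estimated correlation. The erythroid list held 1.47% and 2.68% of all TPM in the E18 samples. Without either E18 sample fewer of these genes met the filter, and 8 erythroid, 5 neutrophil, 4 megakaryocyte and 14 progenitor markers rose, and Tfr2 did not pass (adjusted p = 0.0606 without sample 0 and 0.129 without sample 1).

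Of 26 stellate cell and fibroblast markers 25 rose at E18 (23 rose and 1 fell with median-ratio scaling), of 17 lymphocyte markers 16 rose (15), and of 22 cholangiocyte and ductular markers 18 rose (15 rose and 2 fell). Camera adjusted p was 0.00022, 0.0022 and 0.0304 for the 3 lists, and 0.538, 0.545 and 0.538 with an estimated correlation. Without normal fed sample 0 or sample 1 the ductular list did not pass (camera adjusted p = 0.106 and 0.117). Without E18 sample 0 or sample 1 only 6 lymphocyte markers met the filter, 5 of them rose each time, and that list did not pass (0.0762 and 0.147). Of 25 immediate early genes 21 rose at E18 (15 rose and 3 fell with median-ratio scaling), and the list did not pass by camera (adjusted p = 0.0924, and 0.791 with an estimated correlation). It passed with median-ratio scaling (camera adjusted p = 0.0173), with the correction for exon length (0.00145), without DDC fed sample 0 or sample 1 (0.0433 and 0.0435), and without E18 sample 0 or sample 1 (0.0368 and 0.0156).

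In all, 9020 genes were higher and 1815 lower at E18 of 14307 tested. The median fold change was 1.06, and median-ratio scaling, which lowered fold changes by a median of 1.06, gave 5456 higher and 4520 lower. Of the 9020 genes, 173 were lower under that scaling, and 422 with a correction for exon length chosen after the data were seen. The difference followed total exon length across 10048 genes (Spearman rho = 0.23). Its median was 0.24 in the 20% of genes with the shortest total exon length and 1.34 in the 20% with the longest. By camera 18 lists were higher and 18 lower of 47; with an estimated correlation none passed (1 at an unadjusted p under 0.05), and fry called 41.

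DDC fed adults against E18 asks which genes differ between injured adult and fetal hepatocytes; the normal fed samples enter this comparison through the variance of the fit. Among the genes farthest above E18 were Cyp2c29 at 4059 ± 219 against 0.0769 ± 0.003 TPM (11.88 ± 0.29, adjusted p = 1.2e-06), Gstm3 at 6589.7 ± 626 against 4.95 ± 2.10 TPM (10.16 ± 0.41), Cyp2a5 (9.99 ± 0.32), Gsta1 (9.76 ± 0.23) and Cyp1a2 (9.63 ± 0.33). Of 32 cytochrome P450 genes 25 were higher with DDC and 6 lower (25 and 6 with median-ratio scaling; camera adjusted p = 4.3e-10, and 0.579 with an estimated correlation). Cyp3a11, 1 of the 6, is listed at 0 in the DDC fed samples and at 46.1 TPM at E18, and the glutathione transferase Gstm1 at 0 and 238 TPM. The genes farthest below E18 were those of blood cells, S100a9 at 1.11 ± 0.13 against 31350 ± 3243 TPM (-13.86 ± 0.19), S100a8 (-13.32 ± 0.22), Hbb-bs (-12.66 ± 0.33), Ngp (-12.12 ± 0.19) and Hba-a1 (-11.72 ± 0.40). Krt8 (3.93 ± 0.42), Krt18 (3.25 ± 0.33), Sox9 (2.33 ± 0.27) and Ccnd1 (2.62 ± 0.33) were higher with DDC, and Spp1 did not pass (-0.44 ± 0.23, adjusted p = 0.13). Srsf1 was lower with DDC (-2.16 ± 0.21, adjusted p = 0.00015), as were Nf2 (-1.24 ± 0.23) and Mki67 (-4.37 ± 0.22), while Esrp2 did not pass (0.60 ± 0.26, adjusted p = 0.0766) and Yap1 was higher (0.99 ± 0.29, adjusted p = 0.0211). With normal fed sample 0 or sample 1 left out Esrp2 passed (adjusted p = 0.0343 and 0.034), and without DDC fed sample 0, DDC fed sample 1 or E18 sample 1 Yap1 did not (0.095, 0.0897 and 0.159).

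SR, hnRNP, spliceosome and ribosomal protein genes were lower with DDC than at E18. Whether hepatocytes or the blood cells of the E18 samples carry these differences was not tested. All 21 SR factors (17 with median-ratio scaling), 28 of 29 hnRNP proteins (24), 48 of 55 spliceosome genes (31 lower and 1 higher) and 71 of 75 ribosomal proteins (13) were lower. Camera adjusted p was 0.00079, 0.00055, 0.00022 and 0.00023, and 0.579, 0.640, 0.579 and 0.808 with an estimated correlation. Of 44 G2/M genes 43 were lower and Spc24 was higher (0.60 ± 0.20; 42 and 1 with median-ratio scaling; camera adjusted p = 1.4e-09, and 0.579 with an estimated correlation). Of 33 NRF2 targets 23 were higher and 4 lower (24 and 2 with median-ratio scaling), of 37 urea cycle and amino acid genes 32 were higher (36), and of 19 hepatobiliary transporters 17 were higher (17). The camera test gave an adjusted p of 4.3e-10, 5.2e-15 and 1.9e-10, each 0.579 with an estimated correlation. YAP/TEAD targets went both ways, with 6 higher and 10 lower of 22 (7 and 7 with median-ratio scaling; camera adjusted p = 0.626, and 0.922 with an estimated correlation). Leaving out any DDC fed or E18 sample gave 3 or 4 of these targets higher and 4 to 8 lower. Without DDC fed sample 0 or sample 1, 24 and 39 ribosomal proteins were lower, and without E18 sample 1, 34, and Spc24 did not pass without any 1 of these 4 samples (adjusted p from 0.0779 to 0.269).

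In all, 2532 genes were higher and 6723 lower with DDC than at E18, and 3925 and 4945 with median-ratio scaling, which raised fold changes (median shift -0.48 for deposited minus scaled values). With only these 2 groups in the fit, 3284 were higher and 7895 lower. By camera 18 lists were higher and 16 lower of 47; with an estimated correlation none passed (none at an unadjusted p under 0.05 either), and fry called 38. Without DDC fed sample 0, DDC fed sample 1 or E18 sample 1, 1609, 1584 and 1586 genes were higher, and without E18 sample 0 or sample 1, 3667 and 3302 were lower.

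The overlap of both comparisons asks whether DDC fed and E18 hepatocytes differ from normal fed ones in the same genes. There were 3972 genes higher in both, against 3087 for independent lists of those sizes, and 348 lower in both, against 55.7 (Fisher's exact test, odds ratios 3.71 and 32.3, p = 7.2e-243 and 8.3e-235). Opposite directions held 215 genes higher with DDC and lower at E18, against 621, and 29 lower with DDC and higher at E18, against 277. Both comparisons share the 2 normal fed samples, so part of the excess may come from them. Unchanged groups simulated against the same controls gave a median correlation of 0.501 across genes (0.467 to 0.557 over 100 draws) beside the observed 0.456. The simulated covariance of the fold changes had a median of 0.0445, and the observed covariance was 0.912. The draws give all groups the same spread, while the normal fed samples spread more than the others. Their median absolute log2 difference was 0.37, against 0.125 for DDC fed and 0.17 for E18 samples. The simulated covariance may therefore be too low. Simulated draws held no genes higher in both and 0 to 1 lower in both. As no gene was changed in these draws, hardly any could be called. These counts therefore cannot show how much the shared samples add to the excess. The draws also vary each gene separately, and Fisher's exact test treats genes as independent. In a split chosen after the data were seen, each comparison had 1 normal fed sample of its own, which is assumed to vary like the other groups. With sample 0 for DDC and sample 1 for E18, 3895 genes were higher in both and 422 lower, against 3245 and 95.4 for independent lists (covariance 0.879), and with the samples exchanged 5723 and 486, against 5067 and 160 (0.789). Opposite directions then held 416 and 1052 genes, against 244 with both samples in both comparisons. With median-ratio scaling 2189 genes were higher and 1307 lower in both. Without normal fed sample 0 the counts were 6622 and 600, without DDC fed sample 0 2149 and 191, and without DDC fed sample 1 2061 and 205.

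Higher in both were 43 of 44 G2/M genes, 32 of 37 cytoskeletal genes, 25 of 25 macrophage markers and 15 of 22 YAP/TEAD targets, beside 3972 of 14307 genes overall. So were 32 of 40 G1/S, 23 of 24 endothelial, 22 of 26 stellate and fibroblast, 17 of 25 immediate early and 14 of 22 hematopoietic progenitor genes. No ribosomal protein or ribosome biogenesis gene was higher in both. In which cells these genes rose was not tested. Lower in both were 15 of 22 male-biased genes, beside 348 genes overall. The E18 pools held cells of both sexes, and how much of the fall of the male-biased genes comes from their female cells was not tested. Differences between lists were not tested. Of 33 NRF2 targets 11 were higher in both and 11 were higher with DDC and lower at E18: Gclc, Gsta1, Gsta2, Gsta4, Gstm2, Gstm3, Gstm4, Ephx1, Abcc3, Cbr1 and Aox1 (all listed here after their values were seen). Without DDC fed sample 0 or sample 1 the rises of Gsta4, Cbr1 and Aox1 did not pass (adjusted p from 0.0514 to 0.109). The fall of Gclc at E18 did not pass without normal fed sample 0, E18 sample 0 or E18 sample 1 (0.0568, 0.115 and 0.094), nor that of Gstm4 without E18 sample 1 (0.110) or of Abcc3 without E18 sample 0 (0.0747). Of 32 cytochrome P450 genes 5 were higher with DDC and lower at E18: Cyp2a5, Cyp2b10, Cyp2c29, Cyp2c38 and Cyp2c39. The rise of Cyp2c29 did not pass without DDC fed sample 0 or sample 1 (0.0816 and 0.0651).

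**Figure D3:**
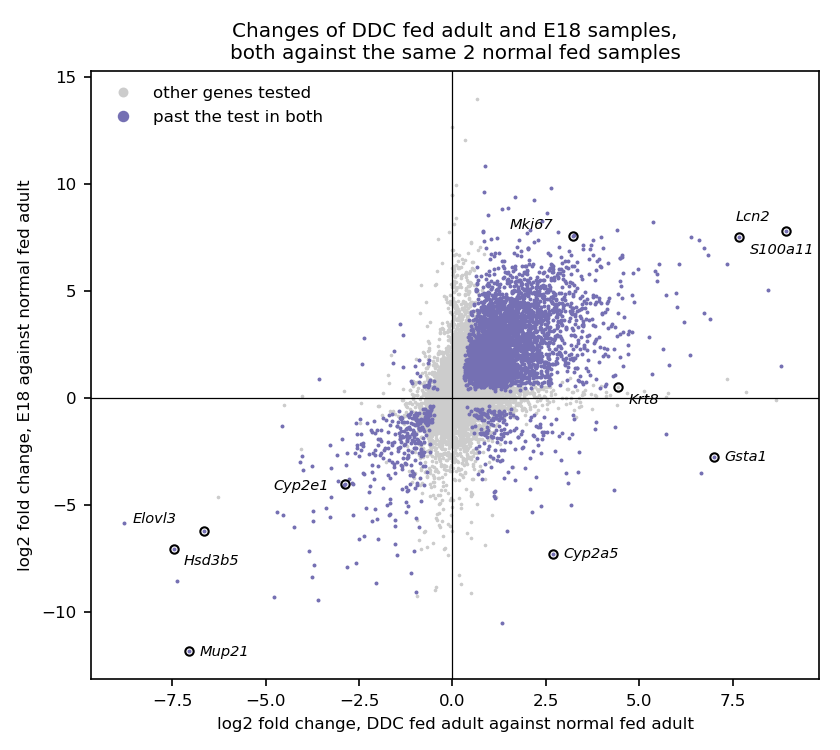
Log2 fold changes of DDC fed (horizontal axis) and E18 (vertical axis) samples against the same 2 normal fed samples; points are genes tested that no group lists at 0, and purple points pass the test in both. Lcn2 (8.93 and 7.79) lies in the upper right, Mup21 (-7.06 and -11.86) in the lower left, and Gsta1 (6.99 and -2.77) and Cyp2a5 (2.70 and -7.30) in the lower right.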

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

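Of the alternatives here, 4 were chosen only after the data were seen: leaving out genes listed at 0, protein-coding genes alone, the correction for exon length, and the split of the normal fed samples. Quantile normalization, a pseudocount of 5, no filter, the 0.01 threshold, the other variance priors, only the groups compared and protein-coding genes alone were run for genes and not for lists or the overlap, and the exon-length correction, the rescaling and the filter on mean TPM not for the overlap. Of those run for each, only the alternatives named below moved a count of genes, of lists or of the overlap by more than 1.5 times, and where no reason is given the cause was not tested.

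For DDC fed against normal fed adults (4896 higher, 439 lower), median-ratio scaling gave 2907 and 1700, quantile normalization 2087 and 2059, the exon-length correction 2531 and 1693, and a threshold of 0.01 2788 and 244. A fold change of at least 2 gave 3154 higher, and a mean of at least 5 TPM, which tests fewer genes, 261 lower. Without 1 sample the counts ran from 2375 to 7985 higher, with the lowest without DDC fed sample 1 and the highest without normal fed sample 0, and from 220 to 917 lower. For E18 against normal fed adults (9020 and 1815), the scalings gave 5456 and 4520, 4576 and 5234, and 4827 and 4808 in the same order. For DDC fed adults against E18 (2532 and 6723), they gave 3925, 4586 and 4553 higher, a mean of at least 5 TPM gave 4299 lower, and without 1 sample 1584 to 3277 were higher and 3302 to 7906 lower. In the overlap, median-ratio scaling gave 2189 higher and 1307 lower in both, a fold change of at least 2 gave 2307 higher in both and 117 in opposite directions (244 otherwise), the split of the normal fed samples gave 416 and 1052 in opposite directions, and without 1 sample the ranges were 2061 to 6622, 191 to 600, and 106 to 521 in opposite directions.

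With the estimated correlation 0, 0 and 0 lists passed in the 3 comparisons by camera, and fry called 13 for DDC fed against normal fed adults. The camera test of the SR list turned to lower with median-ratio scaling (adjusted p = 0.0493). Fry, which does not compare a list with other genes, gave the opposite direction to camera for other lists too; of those that camera or fry called, there were 6 for DDC fed against normal fed adults: ribosome biogenesis (adjusted p = 0.594), complement and coagulation (0.851), hepatocyte transcription factors (0.772), pericentral (0.892) and periportal genes (0.267) and erythroid markers (0.889). For E18 against normal fed adults it did so for gluconeogenesis (0.893), cholesterol synthesis (0.744), the unfolded protein response (0.0037), plasma proteins (0.176) and mitochondrial mRNAs (0.000299). For DDC fed adults against E18 it did so for the unfolded protein response (0.0143), the cytoskeleton (0.0124), plasma proteins (0.118), female-biased genes (0.0288) and ductular markers (0.0218).

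Among named genes that passed in the main fit or in the alternative, log2 fold changes reversed as follows. For DDC fed against normal fed adults, Hnrnpl was -0.037 with median-ratio scaling, and Alas1 ran from -0.94 without normal fed sample 1 to 0.95 without sample 0. For E18 against normal fed adults, median-ratio scaling gave Eif6 -0.48, Fech -0.075, Lsm6 -1.04, Nqo1 -0.49, Prpf19 -0.088 and Rbpms -0.86. Quantile normalization gave Cbr3 -0.91, Ly6d -0.26, Nqo1 -1.22, Slc51b -1.55, Sox9 -1.33, Sprr1a -0.90, Srrm4 -1.43 and Tead1 -0.29. The exon-length correction gave Ddx3y -1.09, Eif6 -0.13, Fech -0.38, Lsm6 -0.93, Nf2 -0.16, Nqo1 -0.11, Prpf19 -0.23, Rbpms -0.99, Sox9 -0.73, Srrm4 -1.18, Tead1 -0.0025 and Tgfb2 -0.075. It also gave Mup3 -0.44, a fitted value and no fold, since the normal fed samples list that gene at 0. For DDC fed adults against E18, Tead1 was 0.79 with quantile normalization and 0.74 with the exon-length correction, which gave Srpk2 0.16.

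Values of named genes under the alternatives were counted as kept if they stayed on the same side of the threshold. Their direction had to stay too, but only where they passed in the main fit or in the alternative. Kept were 3058 of 3268 for DDC fed against normal fed adults, 3185 of 3325 for E18 against normal fed adults and 3160 of 3325 for DDC fed adults against E18. Of the values of lists, 664 of 745, 662 of 746 and 678 of 745 were kept by the same count. The replicate block gave 5102, 9157 and 2686 higher and 498, 1921 and 6801 lower; deviations from the group means under the same number correlated at 0.233, 0.139 and 0.0605 between groups, and the labels pair no samples. Without the depth of the samples, the limit it sets on low values is unknown. In the simulated test no gene changed by 1.5-fold was recovered in either comparison with normal fed adults and 2% were for DDC fed adults against E18. That test changed 200 genes of 14307, so its adjusted threshold was stricter than that of the data.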

Other observations

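All tests in this part were chosen only after the results they explain were seen. The genes of the next paragraph were also chosen after their values were seen.

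The pancreatic genes Clps, Ctrb1 and Pnliprp1 were at 135, 298 and 139 TPM in E18 sample 0 and at 11.2, 25.8 and 10.2 TPM in E18 sample 1, and are listed at 0 in all adult samples. Xist was at 60.7 and 173 TPM and the Y-linked gene Ddx3y at 43.9 and 16.7 TPM in the E18 pools, while Xist was at 0.0706 TPM or less in the adult samples. Phgdh and Psat1, 2 enzymes of serine synthesis, were at 0.0257 ± 0.009 and 0.317 ± 0.087 TPM in normal fed, 0.243 ± 0.16 and 0.846 ± 0.11 in DDC fed and 79.7 ± 12.7 and 206 ± 54.6 in E18 samples. Asns, which makes asparagine, was at 0.233 ± 0.11, 1.69 ± 0.58 and 122 ± 3.36 TPM. With DDC its log2 fold change was 1.11 ± 0.22 (adjusted p = 0.00903), and 0.89 without DDC fed sample 1, where it did not pass (adjusted p = 0.105). Of the heme genes, Hmox1, which breaks heme down, was at 10.1 ± 1.31 TPM in normal fed, 149 ± 27.3 in DDC fed and 314 ± 66.4 in E18 samples, and the heme transporter Slc48a1 at 22.6 ± 3.95, 137 ± 15.0 and 60.2 ± 10.2 TPM.

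Several of the most abundant liver mRNAs are listed at 0 in whole groups. Protein-coding genes outside the lists of other cells, with a value above 0 in some sample, were ranked by their largest product of TPM and exon length. Of the first 100, 15% were at 0 in both samples of some group, against 1.22% of the next 900 (Fisher's exact test across genes, p = 1.1e-09). Of all genes ranked, only 1 was at 0 in 1 sample of a group and at 10 TPM or more in the other. Of 13 mitochondrial mRNAs, 5 were at 0 in all 6 samples, beside mt-Nd2 at 5602 to 14810 TPM; since these mRNAs are processed from shared precursors, that argues against their absence from the cells. A candidate explanation is that values of genes with very many reads were set to 0 when the table was made, group by group; reads were not analysed here, and no biological explanation was tested for single genes.

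Hepatocyte gene groups were lower at E18 beside higher blood-cell genes. Uniform dilution of hepatocyte mRNA by blood-cell mRNA was tested on 8 hepatocyte lists. The first test, the spread over their 214 members, gave an interquartile range of 1.96 against a bound of 2 and left the question undecided, and the list medians were tested after that. These differed by up to 3.66 on the log2 scale, from -4.68 for cytochrome P450 genes to -1.01 for complement and coagulation (permutation p = 0.00018), which argues against dilution as the whole cause. Blood cells in the E18 samples may still account for part: the log2 ratio of E18 sample 1 to sample 0 lay above the median of all genes for 26 of 27 erythroid genes, with a median 0.63 above it (interquartile range 0.15), and the blood-cell lists held 7.81% and 10.2% of TPM. The difference in age between fetal and adult liver stays open, as untested.

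Ductular, macrophage, endothelial and stellate markers were higher in the DDC fed samples. Bile duct cells carried into the samples would bring Krt7 and Krt19, whose highest value there was 0.2275 TPM beside Spp1 at a mean of 62.1 TPM, which argues against them as the source of Spp1. A smaller share of hepatocytes would raise the other markers alike, and this cannot be told apart from a rise of some of these cell types, of their genes within hepatocytes, or an effect of the diet itself. Among genes at 1 TPM or more in both normal fed samples (19 of 25 macrophage, 9 of 24 endothelial and 8 of 26 stellate genes), the list medians of the log2 ratios differed by up to 1.108 (permutation p = 0.074, 100000 resamples), by 1.35 against normal fed sample 0 alone (p = 0.064) and by 0.68 against sample 1 alone (p = 0.43). A first test on genes at a mean of 0.1 TPM or more gave 1.67 (permutation p = 0.00013), which rests on genes near 0. Only 6 of 22 ductular genes were at 1 TPM or more in both normal fed samples, and no sort that would remove other cells is named in the labels.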
